A study of Mus musculus with 10 samples.

How the data were processed

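RNA from LSK cells was measured on 10 Illumina mouse expression arrays, 1 array per mouse, 5 from control mice and 5 from LysM-KI mice. LSK cells are bone marrow cells that lack lineage markers and carry Sca1 and cKit, the compartment that holds haematopoietic stem cells and multipotent progenitors. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with a DNase I step and checked on a Bioanalyser. Per the labels, biotinylated cDNA was then made with the WT-Ovation Pico kit, an amplification for very small amounts of RNA. The scanner software and the summary of beads into probe values are not given in the sources used here.

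The deposited table that was not normalized holds a linear intensity for each of 45281 probes on each array, with the background still in it and array medians that differ. Beside each intensity the authors deposited a fraction between 0 and 1 under a heading that announces a detection p. These fractions rise with the intensity of their own array (lowest rank correlation across probes 0.99, against at most 0.851 with any other array), so a detection p was taken as 1 minus the deposited fraction. Their steps correspond to 936 negative-control spots per array. The authors' processed values are on a log2 scale, and no source used here states how they were made. Log2 of the quantile-normalized intensities without background correction, minus the median of each probe over the 10 arrays, gave the deposited log2 values within 0.00122, and their column medians ran from -0.000897 to 0.00404. They were used as an alternative only. Subtracting the median of a probe leaves differences between groups as they were. Results on these values and without background correction are therefore in effect the same alternative. All value columns belonged to the 10 samples, and 0 columns belonged to others.

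Intensities were normalized with limma 3.58.1 in R 4.3.3 by its neqc function: normexp background correction with the mean and SD of the negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. An offset pulls the fold changes of dim probes toward 0. Probes with a detection p under 0.05 on at least 5 of the 10 arrays were kept, which left 17245. Gene symbols came from the platform annotation and were updated through Entrez identifiers, 99.8% of which were in the RefSeq gene table. Of the probes on the array, 34885 had 1 symbol, 18 had several and 10378 had none. Probes with several symbols or none were tested but not named. The kept probes included 14104 with a symbol, for 8896 genes.

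Groups and replicate numbers came from the labels, which describe individual mice, so the p-values measure the spread between mice as well as that of sorting, amplification and hybridisation. All mice were 9 to 16 weeks old and carried the strain label LysMCre, the name of a line that expresses Cre recombinase from the Lyz2 locus. The labels do not say which allele was knocked in, and none is assumed here. They give neither the sex of the mice nor the chip each array lay on. The replicate numbers occur in both groups. No pair of arrays with the same number is said to share an animal, a litter or a day, so the groups were compared without pairing.

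Each probe was tested with limma's linear model and empirical Bayes moderated test, two-sided, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. Standard errors are those of this model, with 11.1 degrees of freedom, and its 95% intervals use the same. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists, with the kept probe of the highest mean standing for each gene. Of 36 lists, 32 had at least 5 measured genes and were tested. The list of replication-dependent histones, fixed by older symbols, matched no current symbol, and its match through synonyms was added after the data had been seen. Camera with an estimated correlation and fry, a rotation test, were run beside it. The number of probes detected per array was compared by an exact two-sided permutation test over the 252 ways to divide the 10 arrays. These designs, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The exact permutation test of the mean level of a list per array was added after camera's results had been seen, and its p-values were adjusted over 35 lists.

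The rule for naming genes was as follows. Genes past the adjusted threshold came first. Because fewer than 30 passed, the genes of the probes with the smallest unadjusted p were added until 30 were reached. Up to 4 measured members of each list with the smallest unadjusted p could be named, as could Lyz2, Lyz1, Idh1, Idh2 and genes that differ between the sexes. The rule also lets the probe with the highest mean stand for a gene. The 30 genes were ranked by their probe with the smallest p, which for 11 of them is not the probe with the highest mean, and then both values are given. A probe not detected on any array of a group has only a bound there, so a fold against that group is given as at least N-fold. It sets the mean of the brighter group against the lowest level of detected probes on each array of the other group, or the probe's own level where that is higher.

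The fit was tested on simulated data with the means and residual SDs of the real probes, 20 sets of 17245 probes for the comparison of LysM-KI with control. Probes were drawn independently with the same SD in both groups. In the real data the median SD of control arrays was 1.37 times that of LysM-KI arrays, and erythroid genes had an estimated correlation of 0.67. The rates below may therefore not hold for the real arrays. Planted log2 changes of 1, 2 and 3 were recovered in 10%, 52.9% and 76.4% of cases, and 6.41% of the calls were false. For camera, a shift of the cytokine receptor list by 0.25 among 8896 independent simulated genes was called in 2 of 7 sets, a shift of 0.5 in 7 of 7 and a shift of 1 in 6 of 6, where 2 other lists, not shifted, were also called. The number of arrays limits the precision of every value. Alternatives were other background corrections and normalizations, other filters on dim probes, blocks for replicate number and for sex, array weights, a trended and robust variance, other set tests, and each array left out in turn. Leaving out both Xist-high mice, or the 2 arrays farthest from the rest, was added after the data had been seen. Figures were drawn with matplotlib 3.10.9.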

Results

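Gene expression was measured in LSK cells, the stem and multipotent progenitor compartment of mouse bone marrow, sorted from 5 control and 5 LysM-KI mice. The comparison asks which transcripts differ between LysM-KI and control LSK cells. Both groups were of the LysMCre strain and 9 to 16 weeks old. After normalization the arrays correlated at 0.741 to 0.931 with one another across probes, 0.831 to 0.931 among LysM-KI arrays and 0.748 to 0.840 among control arrays. No 2 arrays were near copies, the smallest mean absolute log2 difference between any pair being 0.513. The first principal component, with 22.02% of the variance, set control replicate 4 apart, and the second, with 14.2%, set LysM-KI replicate 2 apart. Lyz2, the myeloid lysozyme gene whose locus carries Cre in the LysMCre line, had a log2 intensity of 8.85 ± 0.66 (SD, n = 5) in LysM-KI and 8.86 ± 0.67 in control cells, a log2 fold change of -0.01 with a 95% interval from -0.89 to 0.87. Its paralog Lyz1 had a log2 fold change of 0.63 with a 95% interval from -0.08 to 1.33, and 1 of its 2 kept probes had the opposite sign.

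LysM-KI arrays detected 17780 ± 858 probes (SD, n = 5) against 16632 ± 789 on control arrays, a difference of 1148.2 (exact permutation test, two-sided, p = 0.0397). Adjusted with 3 other measures per array, this p was 0.0952. Control replicate 4 had the lowest number, 15234, and LysM-KI replicate 4 the highest, 18801. These were also the only Xist-high mice, with an Xist level of 11.81 and 11.69 on the log2 scale, against at most 7.08 on the other arrays. Without both of them the difference was 543.5 (exact permutation p = 0.143), and without control replicate 4 and LysM-KI replicate 2, the arrays farthest out on the principal components, it was 1136.2 (exact permutation p = 0.0286), both choices made after the data had been seen. The median raw intensity differed by less than the spread between arrays, 124 ± 9.46 in LysM-KI and 122 ± 14.9 in control arrays (SD, n = 5, exact permutation p = 0.865).

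**Figure D1:**
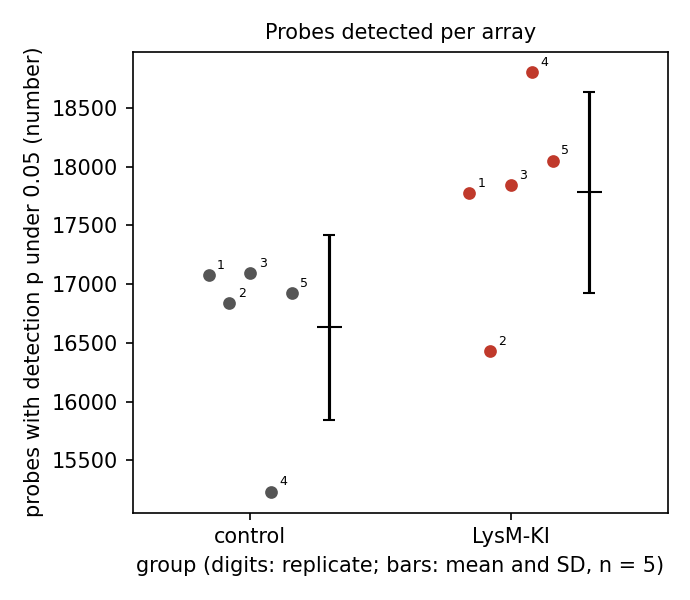
Number of probes with a detection p under 0.05 (vertical axis) on each control and LysM-KI array, with the replicate number beside each point and bars for the mean and SD of 5 arrays. Control replicate 4 lies lowest at 15234 and LysM-KI replicate 2, at 16430, lies below 4 of the control arrays.

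In LysM-KI cells, Abi3, of a family of adaptors that regulate actin, was higher by 3.08 on the log2 scale (SE 0.63, n = 5 per group), an 8.45-fold difference, and Myd88, the adaptor of Toll-like receptors, was higher by 1.76 (SE 0.37). Mzb1, a chaperone for immunoglobulin assembly in B-lineage and plasma cells, was lower, with a log2 fold change of -1.90 (SE 0.32), and so was the zinc finger gene Zc3hav1l at -1.43 (SE 0.25). Abi3 and Myd88 were detected on 3 of 5 control arrays and Zc3hav1l on 3 of 5 LysM-KI arrays. Their fold changes therefore rest partly on values not told apart from background. Each of these 4 genes lay on the same side of the control mean in all 5 LysM-KI mice. They were picked from 17245 probes for their small p, which favours such a pattern. None of them passed the adjusted threshold: limma called 0 of 17245 probes, and the smallest adjusted p was 0.392. At an unadjusted p under 0.05 limma gave 922 probes, 587 higher and 335 lower in LysM-KI cells, where 862 would arise by chance. Cyclic loess turned this split to 430 higher and 450 lower, and median scaling, which moved the median log2 fold change of all kept probes to 0.125, made it 783 and 180.

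**Figure D2:**
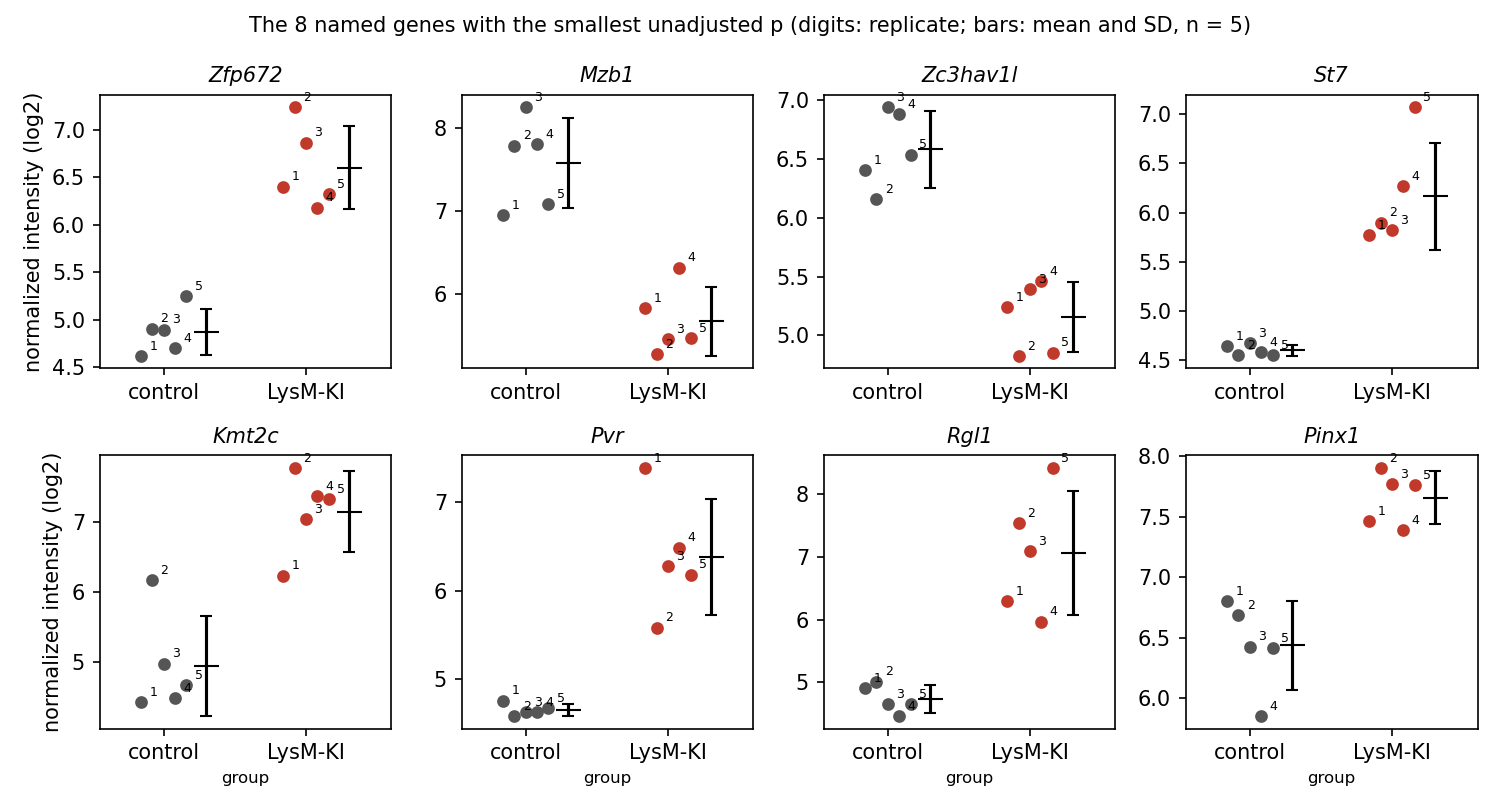
Log2 normalized intensity on each array for Zfp672, Mzb1, Zc3hav1l, St7, Kmt2c, Pvr, Rgl1 and Pinx1, with the replicate number beside each point and bars for the mean and SD of 5 arrays. The groups do not overlap for these genes, which were picked from 17245 probes for their small p, and the smallest adjusted p among them was 0.392.

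Among the 30 genes with the smallest unadjusted p, 23 were higher and 7 lower in LysM-KI cells, with adjusted p from 0.392 to 0.650 in limma. Of the higher ones, 16 were not detected on every control array. The Ral exchange factor gene Rgl1, the cell adhesion receptor gene Pvr (CD155) and St7 were not detected on any control array and were at least 3.51-fold, 2.19-fold and 1.88-fold higher in LysM-KI cells. Dock8, an exchange factor for Cdc42, had a log2 fold change of 1.13 (SE 0.23), and Pinx1, an inhibitor of telomerase, one of 1.22 (SE 0.24), and both were detected on all 10 arrays. One other kept probe of Dock8 had the opposite sign. Pqbp1 had a log2 fold change of 2.19 (SE 0.47) and the RNA-binding protein gene Rbm38 one of 1.80 (SE 0.38).

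The histone H3K4 methyltransferase gene Kmt2c had a log2 fold change of 2.20 (SE 0.39), its probe with the highest mean gave 0.99, and 2 of its 3 kept probes shared the sign. Prdm2, of the PR domain family, was at 2.20 (SE 0.48) with 2 of 2 probes in the same direction. Rbbp7, a histone-binding subunit of several chromatin complexes, was at 1.73 (SE 0.38) on its ranked probe and at 0.36 on its brightest, with 4 of 4 probes in the same direction. The ranked probe of Kmt2c was detected on 1 of 5 control arrays, and those of Prdm2 and Rbbp7 on 3 of 5. These fold changes therefore rest partly on values not told apart from background. The Polycomb and Trithorax list as a whole had a median log2 fold change of 0.17 with 10 of 13 members above 0 (camera adjusted p = 0.739). Its members Ezh2, the H3K27 methyltransferase, Ring1, of the Polycomb repressive complex PRC1, and Kmt2a, an H3K4 methyltransferase, were at 0.50 (SE 0.21), 1.04 (SE 0.49) and 0.37 (SE 0.24). The Polycomb gene Bmi1 was at -0.40 (SE 0.35), below the control mean in all 5 LysM-KI mice.

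Probes of one gene often gave different values. Zfp672 had the smallest p of all, 3.94e-05, with a log2 fold change of 1.73 (SE 0.26) on a probe detected on only 1 control array, and its probe with the highest mean gave 1.12. For St7 that probe gave 1.01, for Fancl, a ubiquitin ligase of the Fanconi anaemia pathway, 0.45 beside 1.62, and for Ssbp2 0.15 beside 1.45. The ranked probe of Dzip3 was not detected on any control array and was at least 1.44-fold higher in LysM-KI cells, while its probe with the highest mean gave -0.78. The probe with the highest mean also had the opposite sign for the sorting receptor gene Sort1 (0.27 beside -1.35) and Dcaf7 (0.00 beside -1.37). The mitochondrial genes Htra2, Timm21 and Dnajc30 were at -1.51, -1.26 and -1.16, and the brightest probe of Timm21 gave -0.08. One of 3 probes of Htra2 had the opposite sign, as had 1 of 2 for Ctnnal1 and Fto, 1 of 3 for Kit and Trp53bp1 and 1 of 5 for Il7r.

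Gene groups of blood lineages were compared next. Genes for cytokine receptors had a median log2 fold change of 0.37 with 11 of 15 members above 0, and their list passed no test after adjustment. The mean level of this list was 8.37 ± 0.12 (SD, n = 5) against 7.93 ± 0.43, and every LysM-KI array lay above every control array (exact permutation p = 0.00794, the smallest these arrays can give, 0.139 adjusted over 35 lists, and up to 0.0714 before adjustment under other scalings). Only this list and that of stroma and endothelium reached this smallest p. With so few lists there, the adjusted p could not fall under 0.05 whatever the size of the difference. The cytokine receptor difference in mean level was 0.45, but 0.26 without control replicate 4. It was 0.25 without background correction and on the authors' processed values, where the median log2 fold change was 0.14. Those settings differ in effect only by the centring of each probe, so here and below they are the same alternative. The genes of the interleukin-6 receptor Il6ra, the interferon gamma receptor Ifngr1 and the G-CSF receptor Csf3r had log2 fold changes of 1.88 (SE 0.73), 0.87 (SE 0.39) and 1.31 (SE 0.71), and 1 of 2 kept probes of Csf3r had the opposite sign. Granulocyte and monocyte progenitor genes had a median of 0.47 with 10 of 16 members above 0, with Gfi1, a repressor that directs granulocyte differentiation, at 0.93 (SE 0.41), Ly86 at 0.85 (SE 0.41) and the granule enzyme gene Mpo at 0.43 (SE 0.25). That median was 0.30 without background correction and on the authors' processed values, and 0.22 without control replicate 5. Erythroid genes had a median of -0.52 with 9 of 12 members below 0, and the B cell and plasma cell genes a median of -0.06 with 6 of 11 below 0. Over all scalings and with each array left out, these medians ran from -0.90 to 0.01 and from -0.15 to 0.09, so both turned sign.

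No list passed camera's adjusted threshold, and 0 of 32 passed with an estimated correlation, with fry or with fry's mixed test. At an unadjusted p under 0.05 camera gave 3 lists, cytokine receptors (p = 0.0260), B cell and plasma cell (p = 0.0276) and erythroid genes (p = 0.0350), each with an adjusted p of 0.374, and their p with an estimated correlation was 0.0812, 0.128 and 0.464. The granulocyte and monocyte progenitor list had a camera p of 0.0523. Adjusted over the list alone, 1 member of the B cell and plasma cell list passed, Mzb1 (limma adjusted p = 9.55e-04), against 0 over all probes. The cytokine receptor, granulocyte and monocyte progenitor, erythroid and Polycomb and Trithorax lists had 0 such members. The other members went both ways: Jchain, which joins immunoglobulin polymers, at -0.77 (SE 0.27), the coactivator Pou2af1 at -0.61 (SE 0.33) and the B cell receptor chain Cd79b at 0.83 (SE 0.43). The erythroid difference rested on single arrays, since without LysM-KI replicate 1 camera called it lower (adjusted p = 0.0148) and without control replicate 2 its direction turned (adjusted p = 0.972), and its adjusted p lay between these values under all other settings fixed before the data were examined. With an estimated correlation, added after the data had been seen, the adjusted p without LysM-KI replicate 1 was 0.947. Without control replicate 4, whose cytokine receptor level was 7.18, camera's unadjusted p for the cytokine receptors was 0.137.

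**Figure D3:**
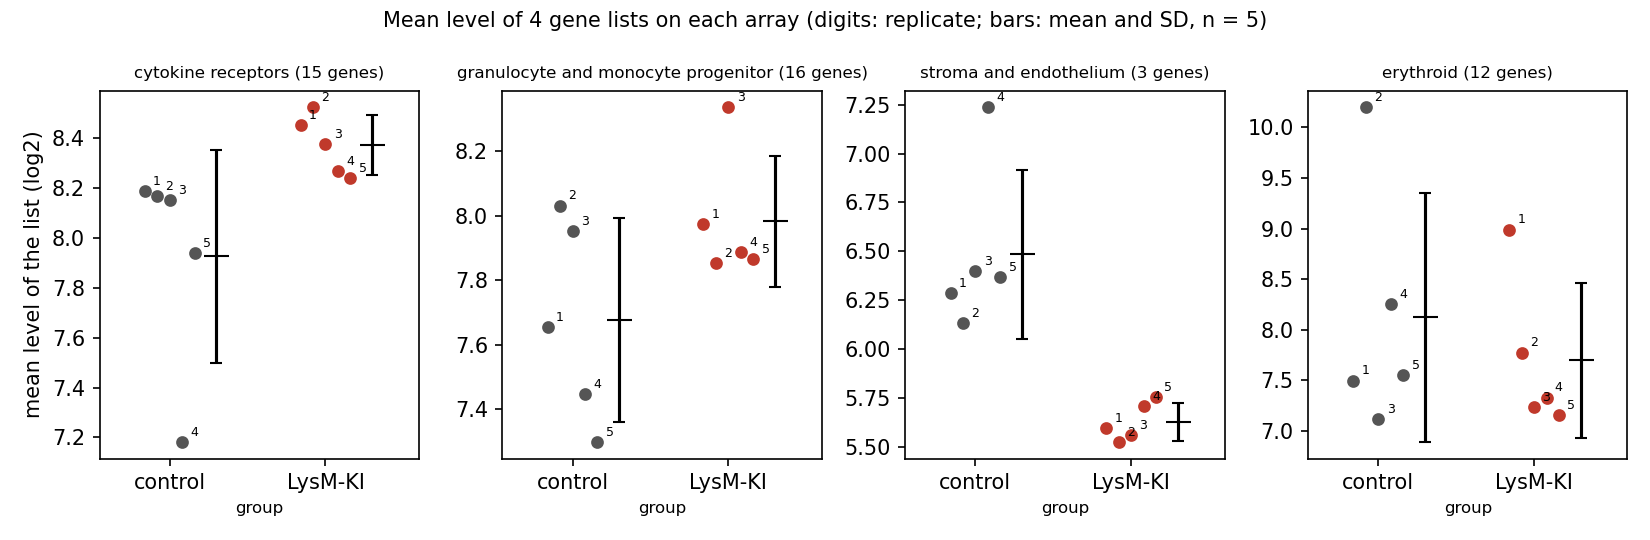
Mean log2 level of the cytokine receptor, granulocyte and monocyte progenitor, stroma and endothelium, and erythroid lists on each array, with the replicate number beside each point and bars for the mean and SD of 5 arrays. Cytokine receptor levels span 8.24 to 8.52 on LysM-KI and 7.18 to 8.19 on control arrays, and the erythroid level reaches 10.20 on control replicate 2.

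The stroma and endothelium list was fixed for cells outside the LSK gate, although Pecam1 (CD31) is also found on haematopoietic stem and progenitor cells. Only 3 of 19 were measured, too few for camera, and their mean level was 5.63 ± 0.10 (SD, n = 5) against 6.48 ± 0.43, lower on every LysM-KI array than on any control array (exact permutation p = 0.00794, 0.139 adjusted over 35 lists). As for the cytokine receptors, this adjusted p could not fall under 0.05 with so few lists at the smallest p. The difference of -0.86 was -0.37 without background correction and on the authors' processed values, and -0.94 with cyclic loess. Adjusted over the list alone, without correction for the number of lists, 1 member passed, against 0 over all probes. This was the receptor gene Pdgfrb, with a log2 fold change of -1.04 (SE 0.33, limma adjusted p = 0.0292 over 3 genes), while the matrix protein gene Sparc had one of -1.40 (SE 0.57). Both were detected on 2 LysM-KI and 4 control arrays. The endothelial adhesion gene Pecam1, detected on all 10 arrays, was at -0.13 (SE 0.26) and at 0.03 with median scaling, and 1 of its 2 kept probes had the opposite sign. Of other lineages, mature neutrophil genes had a median of -0.29 with 5 of 6 below 0, and S100a9 was at -1.19 with an SE of 1.09. Without control replicate 2 the median was -0.03, and without background correction or on the authors' processed values it was -0.11. Megakaryocyte and platelet genes had a median of 0.19 (8 of 11 above 0), with Pf4 at 0.50 (SE 0.33). These 2 lists and those of mast cell, basophil and eosinophil genes (median 0.01), T cell and NK cell genes (-0.01), dendritic cell genes (0.00) and the 3 measured macrophage and monocyte genes (-0.17) gave no member that passed when adjusted over the list alone.

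Genes of the stem cell programme gave medians close to 0. Haematopoietic stem cell genes had a median log2 fold change of 0.12 with 12 of 18 above 0 (camera adjusted p = 0.863). Within it, Pdzk1ip1 was at 1.07 (SE 0.44), Kit, the stem cell factor receptor that defines the gate, at 0.42 (SE 0.29), and Ctnnal1 at -0.56 (SE 0.28). Lymphoid priming genes had a median of -0.06, with the chemokine receptor gene Ccr9 at -1.05 (SE 0.35) and Il7r at 0.31 (SE 0.32). The 5 measured genes of the Hox cluster A and cofactors had a median of 0.07 and a mean of -0.10, with Hoxa7 at 0.57 (SE 0.40). Quiescence genes had a median of -0.08 and the 4 measured Notch pathway genes one of -0.16. Adjusted over the list alone, 0 members of these 5 lists passed.

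Cell cycle and damage genes gave medians near 0. The median was 0.10 for S phase genes (18 of 24 above 0), with the licensing factor Cdt1 at 0.48 (SE 0.31), and 0.04 for G2 and M phase genes. In the latter, the spindle checkpoint kinase Bub1b was at 0.89 (SE 0.28) and the ubiquitin-conjugating enzyme Ube2c at -0.84 (SE 0.28). DNA damage response and repair genes had a median of 0.05, with the methyltransferase Mgmt at -1.15 (SE 0.47), Trp53bp1 at -0.47 (SE 0.22) and Brca2 at 0.75 (SE 0.36). The medians of the p53 targets and the apoptosis regulators were 0.01 and -0.18, with the proapoptotic genes Bbc3 and Bak1 at -1.32 (SE 0.72) and -0.77 (SE 0.27). Bcl2 was at 0.36 (SE 0.24) on its brightest probe, and 3 of its 8 kept probes shared that sign. In all of these lists 0 members passed when adjusted over the list alone.

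Metabolic lists were compared last. TCA cycle and 2-oxoglutarate metabolism genes had a median of 0.15 with 17 of 22 above 0 (camera adjusted p = 0.739), and the NAD-dependent isocitrate dehydrogenase subunits Idh3b and Idh3a were at 1.11 (SE 0.45) and 0.49 (SE 0.28). Idh1, the cytosolic NADP-dependent enzyme, was detected on 3 arrays of each group and had a log2 fold change of -1.39 with a 95% interval from -3.28 to 0.51. Idh2, its mitochondrial counterpart, was at 0.24 with an interval from -0.21 to 0.69. Oxidative phosphorylation genes had a median of 0.09 with 48 of 64 above 0, with Atp5b at 0.36 (SE 0.21), Cox6a2 at 1.38 (SE 0.62) and Ndufs7 at -0.98 (SE 0.39). Glycolysis genes had a median of -0.01, hypoxia-inducible factor targets one of -0.18 with P4ha1 at -1.02 (SE 0.42), and the 2-oxoglutarate-dependent dioxygenases and DNA methyltransferases one of -0.04 with Fto at -0.47 (SE 0.26). Antioxidant and NADPH generation genes had a median of 0.15 and cholesterol synthesis genes one of -0.05, with Stard4 at 0.68 (SE 0.31). In each of these lists 0 members passed when adjusted over the list alone.

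Stress and signalling lists also had medians close to 0. The interferon response list had a median of 0.02 and a mean of 0.19, with Gbp3 at 0.89 (SE 0.40) and Oasl2 at 1.23 (SE 0.57). The NF-kB and inflammatory response list had a median of -0.04 with Socs3 at -1.25 (SE 0.68), and the unfolded protein and amino acid stress response list one of 0.01 with Pdia4 at -0.71 (SE 0.30). The medians were 0.06 for heat shock genes, -0.03 for immediate early genes and 0.03 for 59 ribosomal protein genes, and 0 members of these 6 lists passed when adjusted over the list alone. No current symbol matched the list of replication-dependent histones as it had been fixed. Matched through older symbols after the data had been seen, 52 such genes were measured, with a median of -0.10 and 36 below 0 (camera p = 0.0183, adjusted p = 0.289 over 33 lists, unadjusted p = 0.478 with an estimated correlation, 0 members past when adjusted over the list alone). That median ran from -0.20 to -0.04 under other scalings and with each array left out. The mean of a list changed sign with the scaling, between -0.15 and 0.12, for lymphoid priming, T cell and NK cell, dendritic cell, G2 and M phase, quiescence, DNA damage, p53 target, glycolysis, hypoxia-inducible factor, dioxygenase, heat shock, unfolded protein, cholesterol synthesis and ribosomal genes. Over all scalings and with each array left out, medians ran from 0.04 to 0.25 for haematopoietic stem cell, 0.06 to 0.35 for Polycomb and Trithorax, 0.07 to 0.23 for megakaryocyte and platelet, 0.09 to 0.20 for TCA cycle, 0.02 to 0.18 for oxidative phosphorylation and 0.04 to 0.19 for S phase genes. They ran from -0.34 to 0.03 for apoptosis regulators, -0.31 to 0.07 for Notch pathway, -0.38 to -0.06 for hypoxia-inducible factor targets, -0.28 to -0.04 for macrophage and monocyte and 0.02 to 0.22 for antioxidant genes. Median, mean and camera direction differed in sign for the Hox, mast cell, T cell and NK cell, dendritic cell, G2 and M phase, DNA damage, p53 target, heat shock, unfolded protein and ribosomal lists.

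**Figure D4:**
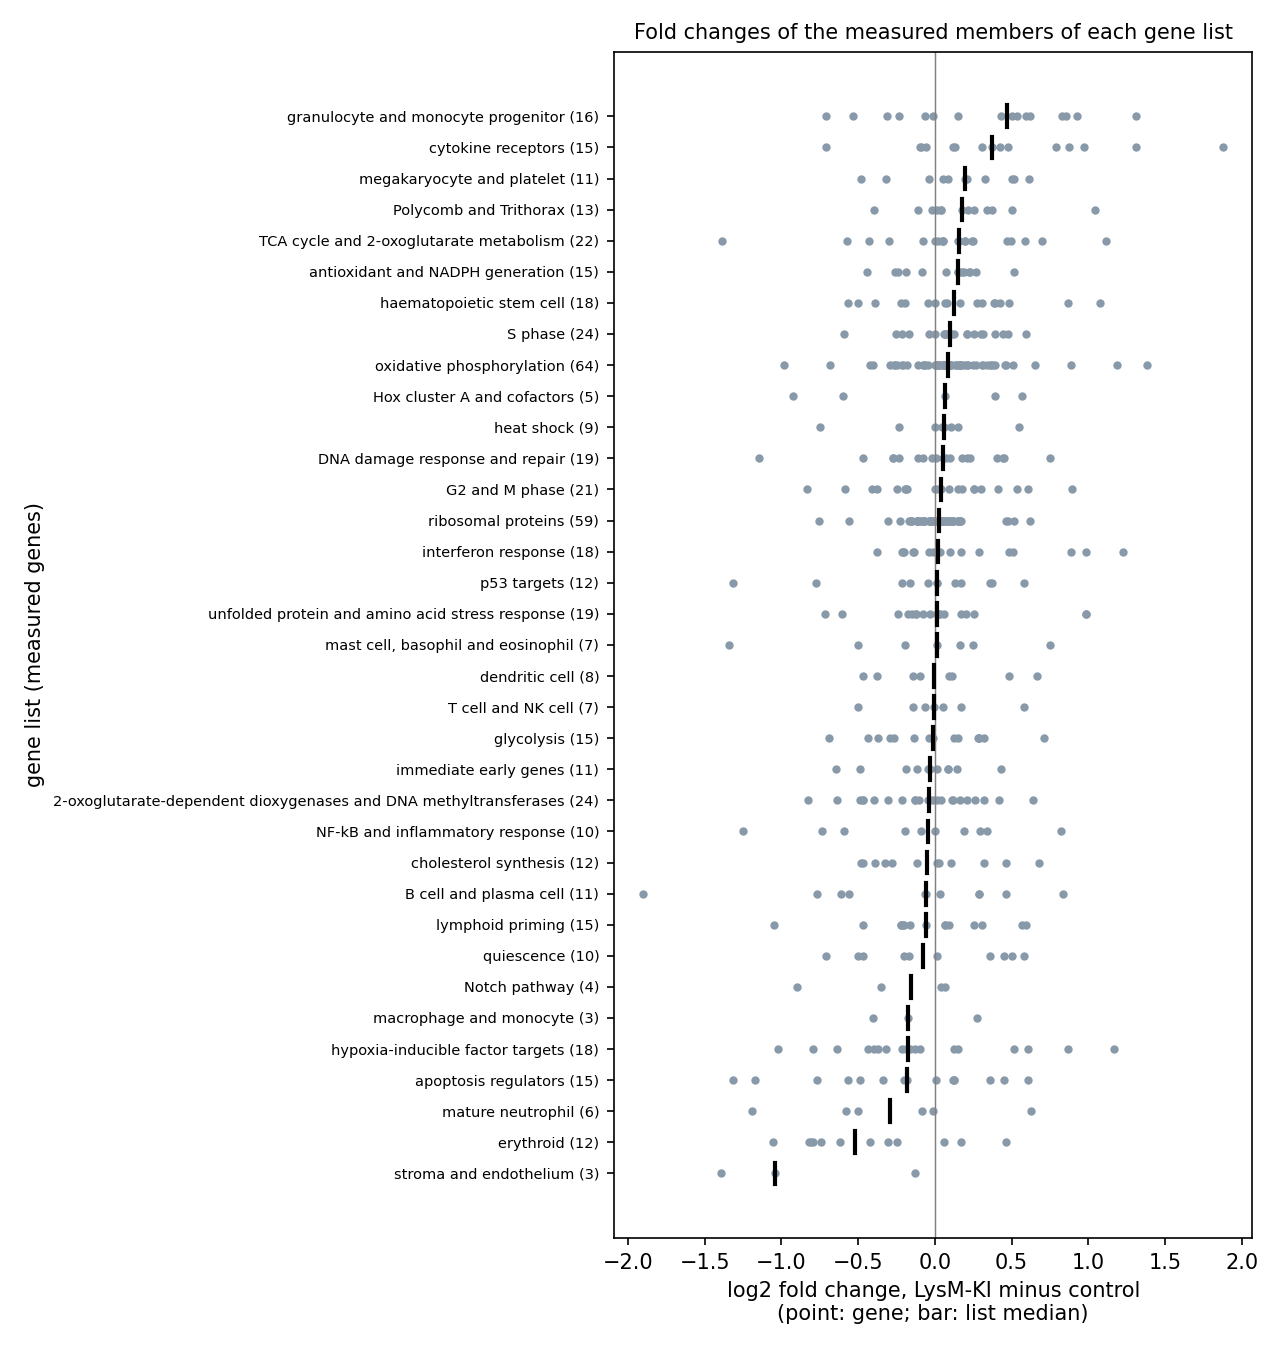
Log2 fold change of LysM-KI against control (horizontal axis) for each measured member of 35 gene lists, 1 point per gene, with a bar at the median of the list and the number of measured genes beside its name. Medians run from -1.04 for stroma and endothelium to 0.47 for granulocyte and monocyte progenitor genes, and the members of most lists lie on both sides of 0.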

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

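Of the tests in this part, those of control replicate 4, of scan brightness and of random loss in the amplification were chosen only after the result they bear on was seen, as were the splits for a count of 0, the splits with an estimated correlation and the requirement that a bound be passed by more than its spread.

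In the groups of 5 arrays, 18 of 238 held a value far from the other 4, where chance flags about 1 in 20 groups, or 12. Control replicate 4 was one of these for 15234 detected probes. Its mean log2 level was 7.24 for stroma and endothelium genes, 7.27 for hypoxia-inducible factor targets and 7.18 for cytokine receptors, and its level of Nfe2 was 8.68 and of Pdia4 10.07. LysM-KI replicate 2 lay lowest in its group for cholesterol synthesis genes at 6.57, Pf4 at 7.86, Cox6a2 at 7.66 and Pdia4 at 7.83. LysM-KI replicate 3 lay highest for granulocyte and monocyte progenitor genes at 8.34 and for Gapdh at 10.79. LysM-KI replicate 5 lay highest for B cell and plasma cell genes at 8.49, and LysM-KI replicate 1 for Hbb-bs, a globin gene, at 11.25. Control replicate 5 lay lowest for S phase genes at 8.92 and for the 2-oxoglutarate-dependent dioxygenases and DNA methyltransferases at 7.60. Eif2s3y, on the Y chromosome, was at 4.41 in control replicate 4 and 4.57 in LysM-KI replicate 4, the Xist-high mice of the groups.

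Of the explanations for the 1148.2 more probes detected on LysM-KI arrays (exact permutation p = 0.0397), brighter scans of these arrays are not settled. The median raw intensity differed by only 1.54 beside an SD of 14.9 among control arrays. At most 18801 of 45281 probes were detected on any array, so this median reads mostly background and cannot decide the question. Whether control replicate 4 alone is the source stays open, since without it the difference was 798.8 (exact permutation p = 0.119), which passes the bound set for excluding this source by less than the spread between arrays. More random loss of transcripts in the amplification of control samples is not settled either. Among the dimmer probes control arrays spread 1.32 times as much as LysM-KI arrays, but 7 of 100 splits of the arrays were as far from 1. Without control replicate 4 this ratio was 1.17. Among the brighter probes it was 1.40 over all arrays, so the wider spread of control arrays was not particular to dim probes. An effect of the genotype stays open and untested. The labels give no sex, but by Xist and Eif2s3y it appeared balanced, with 1 Xist-high mouse in each group. The placing of control replicate 5, with an intermediate Xist level of 7.08, is less certain. The Xist-high mice hold the lowest and the highest count, so leaving them out lowers the difference whatever its cause. The 543.5 without them shows that much of the difference rests on 1 mouse per group, but it cannot tell the causes apart.

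Of the 922 probes at an unadjusted p under 0.05, 63.7% were higher in LysM-KI cells, and 5 of 100 splits of the arrays, the real one included, were as one-sided, with 67.2% the highest of the others. Lower detection on control arrays is not excluded as the source, since among probes detected on all 10 arrays the share was 60.95% (exact 95% interval 56.2% to 65.5%, probes not being independent), against 66.2% among the rest. A shift of all probes left by the normalization is likewise open: after subtracting the median log2 fold change the share was 56.4%, between the bounds of 55% and 60% set for it. The choice of scaling moved the share from 48.9% with cyclic loess to 81.3% with median scaling, so both the size and the direction of the imbalance depend on that choice. Its size also varied with the filter on dim probes. With no filter 984 of 1848 such probes were higher, and with detection required on all 10 arrays and a separate fit 320 of 531 were. A real shift of many transcripts in LysM-KI cells was not tested apart from these.

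Chance cannot be excluded for the number of probes at an unadjusted p under 0.05, since 19 of 100 splits of the arrays gave as many as the real 922, up to 1407. For the counts past an adjusted p of 0.05, the real split gave 0 probes and 0 lists, which 100 of 100 splits match by construction. Other splits gave up to 3 probes and, with camera, up to 7 lists, and 51 of the 100 gave at least 1 list. With an estimated correlation camera gave 0 lists for the real split, and 1 of the other splits gave any, with 1 list.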

How the results depend on the processing

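Leaving out both Xist-high mice and leaving out the 2 farthest arrays were chosen only after the results were seen, as were all alternatives for the mean levels and medians of gene lists, the estimated correlation with an array left out and the matching of histones, and all other alternatives were planned. The count of probes past the adjusted threshold was 0 under every alternative run, and that of lists was 0 except without LysM-KI replicate 1, so that it ran from 0 to 1 when each array was left out. With an estimated correlation it was 0 with each array left out, and with the histone list matched through older symbols it was also 0. The count at an unadjusted p under 0.05 was 1848 with no filter on dim probes and 531 with detection required on all 10 arrays, which test more and fewer probes. The 1848 were fewer than 0.05 of the 45281 probes on the array, the share that chance would give. The difference in detected probes ran from 798.75 to 1485.7 when each array was left out, past an exact p of 0.05 only without LysM-KI replicate 2. Fewer arrays allow fewer regroupings, and the cause was not tested further. It was 543.5 without both Xist-high mice (exact permutation p = 0.143), 1136.2 without the 2 farthest arrays (exact permutation p = 0.0286) and 932.6 at a detection threshold of 0.01 (exact permutation p = 0.0476). With the replicate number as a block, a paired exact sign-flip permutation test of the same 1148.2 gave p = 0.125. With 5 pairs that test cannot give a p under 0.05 whatever the data, so it does not weigh against the difference. In the same block limma gave 0 probes, 0 lists and 980 probes at an unadjusted p under 0.05. Arrays of the same number correlated at -0.0305 to 0.0605 in their deviations, and 1 of 5 LysM-KI and 1 of 5 control arrays matched best with their own number, so the numbers were not taken to pair the mice. A block for the chip was not run, because no chip is given. The mean level differences of the cytokine receptor and the stroma and endothelium lists ran from 0.26 to 0.51 and from -0.95 to -0.68 when each array was left out. Of 1888 values of 80 named genes under an alternative, 1876 kept their sign, and Egr1, Eif2s3y, Lyz2 and Pecam1 did not. Egr1 turned to 0.0091 without the 2 farthest arrays. Eif2s3y turned to -0.40 with array weights and -0.97 without the 2 farthest arrays, and ran from -0.67 to 1.38 when each array was left out. Lyz2 turned to 0.16 with array weights, 0.13 without both Xist-high mice and 0.40 without the 2 farthest arrays, and ran from -0.18 to 0.25 when each array was left out. Pecam1 turned to 0.030 with median scaling and ran from -0.24 to 0.018 when each array was left out. The main values of all 4 lay within 1 SE of 0, and the cause was not tested. Probes close to the background limit the detection count and the fold changes of dim genes.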

Other observations

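The tests of immediate early genes by replicate number and of second probes were chosen only after the results were seen.

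The globin gene Hbb-bs had a log2 level of 12.43 in control replicate 2, 11.25 in LysM-KI replicate 1 and 10.82 in control replicate 4, and lay between 8.70 and 9.51 in the other mice. S100a9, a calcium-binding protein abundant in neutrophils, ranged from 5.57 in control replicate 1 to 11.57 in control replicate 2. The mean level of the mature neutrophil list was likewise highest in control replicate 2, at 8.58. Mature erythroid cells and neutrophils are cells that the lineage-negative gate should remove.

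Of the genes that differ between the sexes, Xist and Eif2s3y placed 1 mouse of each group apart from the rest. Xist was at 11.81 in control replicate 4 and 11.69 in LysM-KI replicate 4, where Eif2s3y was at 4.41 and 4.57. In the other 8 mice Eif2s3y was between 8.87 and 10.02, and Xist between 4.68 and 5.17 except in control replicate 5, where it was 7.08. Control replicate 5 also had the lowest Eif2s3y of these mice, 8.87.

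Immediate early genes, transcribed within minutes of a stimulus, followed the replicate number more than the genotype in appearance. Their mean log2 level was 7.73 and 7.68 in LysM-KI replicates 1 and 2, 8.28 and 7.93 in control replicates 1 and 2, and between 8.31 and 9.07 in replicates 3 to 5. A hypothesis is that samples with the same number were sorted or handled together. After the mean of each group was subtracted, the mean absolute difference between arrays of the same number was 0.346 against 0.601 over all pairings. However, 20 of the 120 possible pairings were as low (exact permutation p = 0.167, 0.739 adjusted over 32 lists). Shared sorting or handling of samples with the same number may or may not lie behind it and cannot be told apart from chance.

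If the genes with the smallest p reflect real changes of expression, their other probes should share the direction. Of 37 other kept probes of 20 such genes, 21 or 56.76% had the same sign (exact 95% interval 39.5% to 72.9%), against 58.8% for the other genes. The interval treats the probes as independent, which those of the same gene are not, so it may be too narrow. Their median log2 fold change in the direction of the named probe was 0.20, beside 1.59 for the named probes, and 4 had both the same sign and an unadjusted p under 0.05. The signs of the second probes therefore lend these genes no added weight, though the interval is too wide to exclude that some of them changed. Whether 4 such probes are more than chance would give was not tested.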
